A study of Mus musculus with 16 samples.

How the data were processed

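The series holds 16 Affymetrix Mouse Gene 1.0 ST arrays in 8 groups of 2, from total RNA of cells sorted from male mice on a FACSAria into TriZol and amplified with the Ambion WT Expression Kit. Per the labels, the authors summarised the arrays with RMA in Affymetrix Power Tools, and no version of either was stated. The deposited value is an intensity per probe set on a linear scale, and every value was above 0. Array medians lay between 173.57 and 193.7, lowest values between 7.1 and 7.93, and highest values between 16453.18 and 21209.81. The ratio of the upper to the lower quartile ran from 5.49 to 7.52. Whether all 16 arrays were normalised together is not stated. The log2 of each deposited value was used from there on, with no further scaling. An array has no read depth, and the number of arrays limits the precision.

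Of 24922 probe sets, 21425 carried exactly 1 gene symbol, 1399 carried several and 2098 carried none. Names were compared with the RefSeq annotation of GRCm38.p6 by Entrez identifier, which matched 21347 probe sets and changed 0 symbols. A gene with more than 1 probe set (921 of 19752 genes) was represented by the probe set with the highest mean over the 16 arrays. Genes without a probe set of their own symbol, among them Isg15 and H2-K1, are not analysed here. A gene was tested when at least 2 arrays of the fit lay above their own median.

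Groups followed the titles and the labels of each array. Samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 3 models: 10 macrophage arrays in 5 groups, 6 T-cell arrays in 3 groups, and the 12 B10.Q arrays in 6 groups for differences between the cell types. The 11 contrasts were IFNα against its own control, 5 h against 2 h, untreated B10.Q against untreated knockout macrophages, and the difference of responses between knockout and B10.Q macrophages or between macrophages and T cells. Untreated here means B10.Q with vehicle and knockout titled without IFNα. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. All tests were two-sided unless stated. Errors are standard errors (SE) of the log2 difference from the fit, and n is 2 arrays per group throughout. Nothing in the labels states that the 2 arrays of a group came from separate animals, so the p-values measure the spread between these samples. The vehicle pair of each cell type joins 1 array taken at 2 h and 1 taken at 5 h.

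The named genes were up to 15 with the largest rise and up to 15 with the largest fall among called genes whose groups did not overlap in any array, up to 4 members of each gene list with the largest change, and Ifnar1, Ifnar2 and Tyk2. For differences of responses no overlap rule applied, and where no gene passed, the 6 with the smallest p were named. Sets of genes were drawn from 32 lists of pathways and cell type markers. A list was tested with camera, at a preset correlation of 0.01, in each contrast where at least 5 of its genes were tested, which 23 lists reached in at least 1 contrast. This gave 236 tests, adjusted together. Camera with a correlation estimated from the data and fry were run beside it. At the preset correlation 101 of the 236 tests passed, with the estimated correlation 0 passed, and fry called 13. Counts "adjusted over the list alone" use the p-values of the list's own members. The list of GBP and IRG GTPases held Mitd1, which is not a GTPase, and lacked Gm12250, which is one. It was kept as fixed. A fold whose vehicle arrays both lay below the lower quartile of their own array is given with "at least", a rule chosen after seeing the data. Such a value is the point estimate, and "at least" refers to the low vehicle intensity only. The SE still applies on both sides of it. Of the 9 lists too small to test, 8 are given as mean levels per array, and type I and II interferon genes by single genes.

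The grouping, the contrasts, the lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the subtraction of macrophage RNA and the crossed replicate numbers, which were chosen after seeing the data. The alternatives were no filter or a filter at the 70th percentile, quantile normalization, subtraction of array medians, a trend and robust variance model, every probe set, the replicate number of the titles as a block, fits of only the compared groups or of all 16 arrays, and leaving out each array in turn. Groups of 2 arrays allow no test for an extreme array within a group and no informative regrouping of arrays. The procedure was tested on simulated data with 200 changed genes in each of 5 draws per contrast. A 2-fold change was recovered in 95.6% of cases for knockout macrophages, 96.4% for B10.Q macrophages at 2 h, 99.6% for T cells at 2 h and 68.8% for the difference between B10.Q and knockout responses. A 1.5-fold change was recovered in 46%, 47.2%, 86.4% and 10% of cases. The false share of calls lay between 5.09% and 7.71%. The simulated noise was independent between genes and equal over the arrays of a gene, and the changed genes included 4-fold and 8-fold changes. Such data hold no array that stands apart, and many true changes ease the adjusted threshold. The recovered shares therefore do not carry over to the knockout contrast, where 0 genes passed. Of 5 simulated lists moved by 0.5 log2 per contrast, all 5 had an unadjusted camera p under 0.05 in each of the 11 contrasts. Of 5 unmoved lists 1 did for T cells at 5 h against 2 h and 0 in each other contrast. The genes of these lists varied independently, so the check cannot tell whether the preset correlation suits the real lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.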

Results

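Gene expression was measured in mouse peritoneal macrophages (ICAM2+ F4/80+) and in splenic CD4+ T cells (TCRB+ CD4+ CD8-) after a subcutaneous injection of 10000 units of interferon alpha (IFNα), a type I interferon. The series title asks how far the expression of interferon-stimulated genes depends on IFNAR1, a chain of the type I interferon receptor, and on Tyk2, a kinase bound to it. Macrophages came from 6-week-old mice of a C57BL/6 line without Ifnar1 (KO) and from 7-week-old B10.Q/J mice, a strain with a natural mutation in Tyk2. T cells came from B10.Q/J mice. Each of 8 groups held 2 arrays: KO macrophages at 2 h after IFNα, KO macrophages whose titles name no IFNα, B10.Q macrophages and B10.Q T cells with vehicle, and both B10.Q cell types at 2 h and at 5 h after IFNα. The preparation text of the KO pair titled without IFNα states the same 2 h IFNα injection as its partner, and the title was followed. If that text is right instead, both KO groups were treated. 5 of the 6 B10.Q macrophage titles carry the code for spleen, while their source is the peritoneal cavity. The title of T-cell vehicle array 1 begins with the code for B cells. Its level of Cd3e was 12.40 on the log2 scale, its Cd4 was 12.14 and its Cd79b was 8.19, against 12.46, 12.31 and 8.33 in vehicle array 2. Gata6, a transcription factor of peritoneal macrophages, lay between 10.63 and 11.85 in the 10 macrophage arrays and between 6.57 and 7.21 in the 6 T-cell arrays. Array medians lay between 173.57 and 193.7 intensity units. The 2 arrays of a group correlated over genes at r between 0.984 (KO with IFNα) and 0.997. No array of a mouse with intact Ifnar1 and intact Tyk2 is in the series, so the contribution of Tyk2 was not measured.

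In KO macrophages the question is whether IFNα changed any gene without its receptor. The probe set of Ifnar1 read 9.93 and 10.31 in the KO IFNα arrays, 10.26 and 10.09 in the KO arrays titled without IFNα, and 10.09 to 10.46 in the 6 B10.Q macrophage arrays. Untreated B10.Q lay above KO by 0.18 ± 0.15, not called, so this probe set does not check the genotype. The interferon-stimulated genes Mx1 and Ifit1 sat below the array median in all 4 KO arrays. Mx1, an antiviral GTPase, lay between 6.14 and 6.43, and Ifit1, which binds foreign RNA, between 6.11 and 6.43. The difference at 2 h was -0.58 ± 0.25 (SE, n = 2) for Rtp4 and 0.41 ± 0.51 for Ifi205, with no call for either. With limma, 0 of 10531 genes passed an adjusted p of 0.05, and 460 had an unadjusted p under 0.05, where 527 would by chance.

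Several cell cycle genes were among those with the smallest p in the KO arrays, at lower values in the IFNα arrays. Chek1, a checkpoint kinase, had the smallest adjusted p (0.0895) at -0.97 ± 0.12 (0.51-fold). Top2a, which untangles replicated DNA, was at -0.98 ± 0.16, Pole at -0.77 ± 0.12, Mcm5 at -0.80 ± 0.12 and Uhrf1 at -0.82 ± 0.14, each with an adjusted p of 0.174. Axl, a receptor kinase for dying cells, was at -1.11 ± 0.17 and Mt2, a metallothionein, at 1.38 ± 0.23, with the same adjusted p. None of the 25 cell cycle genes tested passed over all genes, and 18 were lower adjusted over the list alone. The list median was -0.65, with adjusted p = 1.36e-29 at the preset correlation and adjusted p = 0.166 with an estimated correlation. KO IFNα array 1 stood apart, with a ratio of upper to lower quartile of 5.49 against 6.31 to 7 in the other KO arrays, and a mean of 13 peritoneal macrophage markers of 11.69 against 11.96 to 12.30 in the 9 other macrophage arrays. MHC class II genes had a median of -0.53, with 0 of 8 past the test over all genes and 4 adjusted over the list alone (adjusted p = 0.119 with an estimated correlation). H2-Eb1 was at -0.87 ± 0.17 and Ciita, the regulator of class II genes, at -0.87 ± 0.26. The list of GBP and IRG GTPases, which attack vacuoles of pathogens, had a median of -0.69 with 0 of 8 called (adjusted p = 0.4999 with an estimated correlation). Array 2 without IFNα lay above array 1 in all 8, by a median of 0.94. Gbp5 was at -0.97 ± 0.43. Antiviral effectors had a median of -0.15, with 0 of 34 called (adjusted p = 0.829 with an estimated correlation). B cell markers were higher in the KO arrays numbered 1. Ms4a1 (CD20) read 7.89 with IFNα and 7.54 without, against 5.80 and 5.88 in the arrays numbered 2 and 5.68 to 5.88 in the B10.Q macrophage arrays. The mean over 9 neutrophil markers was 7.48 in KO array 1 without IFNα, against 6.88 to 7.09 in the other KO arrays. The count rested on single arrays: without KO IFNα array 1 it was 37, without KO IFNα array 2 it was 1191 (282 higher, 909 lower), and without either of the others it was 0. With 1 array left in a group, that array was assumed to vary like the other groups.

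In B10.Q macrophages at 2 h, 84 of 10531 genes rose and 0 fell against vehicle, with 476 at an unadjusted p under 0.05. Mx1 rose at least 37.2-fold (5.22 ± 0.26 log2, n = 2, limma adjusted p = 1.44e-05), from 6.15 and 6.12 in the vehicle arrays to 11.87 and 10.84. Its vehicle values lay below the lower quartile of their arrays (6.30 and 6.31), as did those of Ifit1, Ifit3, Mx2, Rsad2, Ifi205 and Ifi208. The folds of these 7 are therefore given with "at least" and are not ranked. They are point estimates, and the 95% interval of Mx1 began at 4.63 log2. Ifit1 rose at least 29.0-fold (4.86 ± 0.42, adjusted p = 5.42e-04) and Mx2, an antiviral GTPase like Mx1, rose at least 24.7-fold. Rtp4 rose 23.6-fold, Rsad2 (viperin, which makes a chain-terminating nucleotide) at least 19.2-fold, and Usp18, the protease that shuts off type I interferon receptor signalling, 20.3-fold. All 84 genes were higher in both IFNα arrays than in both vehicle arrays, as were 1191 of all 10531 genes. In 3386 genes both IFNα arrays lay below both vehicle arrays, where chance gives 16.7% each way.

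The antiviral effectors held 21 of the 84, out of 34 tested, with 26 higher adjusted over the list alone. Beside the genes above, Ifit3 rose by at least 4.20 ± 0.58, Oasl2 by 3.21 ± 0.34, Cmpk2 by 3.15 ± 0.40, Oas2, a synthetase that activates RNase L, by 2.90 ± 0.28, and Xaf1 by 2.71 ± 0.22. The list median was 1.54 (adjusted p = 0.0807 with an estimated correlation). Of 23 genes for nucleic acid sensing 13 rose, and 16 did adjusted over the list alone, with a median of 1.14 (adjusted p = 0.0807 with an estimated correlation). Ifi205 rose by at least 4.17 ± 0.51, its relative Ifi209 by 2.35 ± 0.30 and Ddx58 (RIG-I, a sensor of viral RNA) by 1.73 ± 0.20. The PARP, TRIM and Schlafen families had 15 of 24 members up, 20 adjusted over the list alone, and a median of 1.07 (adjusted p = 0.0807 with an estimated correlation). Slfn5 rose by 3.32 ± 0.28, Slfn1 by 2.35 ± 0.25, Slfn9 by 2.28 ± 0.32 and Slfn8 by 2.08 ± 0.16. Other large rises were Gm12250, an IRG GTPase that the fixed lists lack (3.11 ± 0.44), and Ifi208 (at least 2.85 ± 0.41).

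Among 21 interferon signalling genes, 3 rose, and 6 did adjusted over the list alone. These were Irf7, the factor that amplifies interferon production (2.70 ± 0.28), and Stat2 (2.07 ± 0.26) and Irf9 (1.62 ± 0.20), members of the complex that binds interferon response elements. The list's median was -0.02 and its mean 0.37, and camera gave an upward direction (adjusted p = 0.254 with an estimated correlation). Ifnar1 was at -0.15 ± 0.15, Ifnar2 at -0.02 ± 0.10 and Tyk2 at -0.03 ± 0.13. The fixed list of GBP and IRG GTPases had 2 of 8 members up, the GTPase Irgm1 (2.37 ± 0.38) and Mitd1 (0.86 ± 0.16), which is not a GTPase, and 6 were higher adjusted over the list alone (median 1.25, adjusted p = 0.200 with an estimated correlation). Iigp1 was at 2.68 ± 0.79 with an adjusted p of 0.412. Of 18 chemokine and cytokine genes, Ccl2, which recruits monocytes (2.30 ± 0.42), and Il15, which sustains NK and memory T cells (1.41 ± 0.24), rose, and 9 were higher adjusted over the list alone (median 0.41, adjusted p = 0.166 with an estimated correlation). Cxcl10 was at 2.05 ± 0.50 with an adjusted p of 0.179. MHC class I presentation had 1 of 20 genes up, H2-T24 at 1.94 ± 0.21, with 2 adjusted over the list alone and a median of 0.14 (adjusted p = 0.334 with an estimated correlation). Tap1, the peptide transporter, was at 1.35 ± 0.33 with an adjusted p of 0.184. Usp18 was the 1 of 15 negative feedback genes that rose (3 adjusted over the list alone), in a list with a median of -0.02, a mean of 0.42 and an upward direction in camera (adjusted p = 0.200 with an estimated correlation). Xaf1 was the 1 of 16 apoptosis genes that rose, with 3 adjusted over the list alone and a median of 0.03 (adjusted p = 0.178 with an estimated correlation). Without vehicle array 1 or vehicle array 2 the count was 36, without IFNα array 1 it was 42, and without IFNα array 2 it was 123. The replicate block gave 75 genes.

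**Figure D1:**
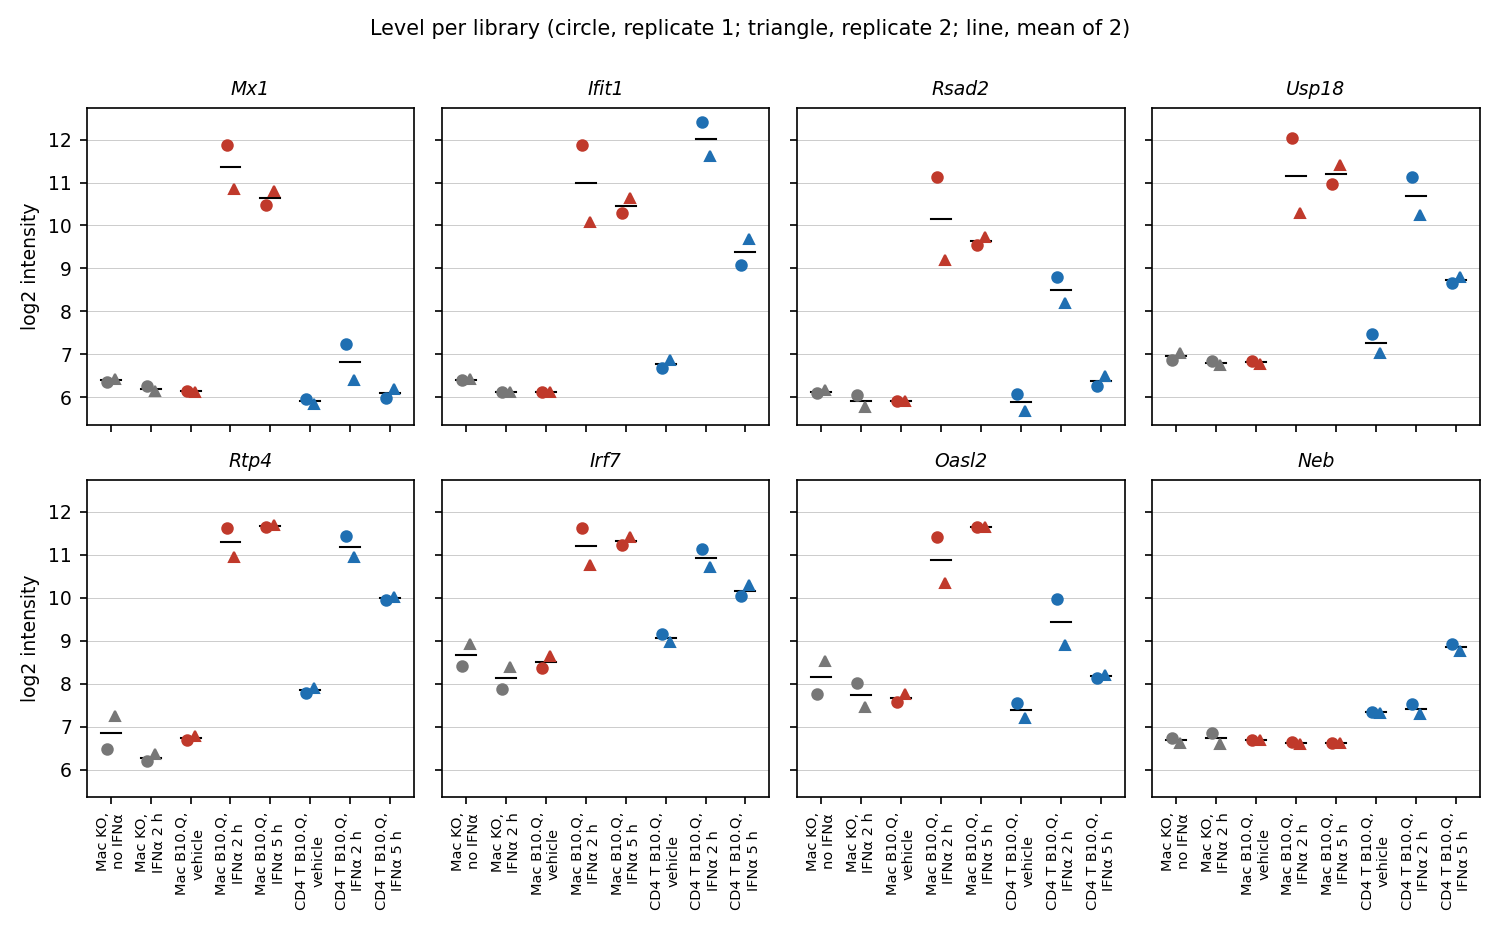
Log2 intensity of interferon-stimulated genes in each of the 16 arrays, 1 point per array, grouped by cell type, strain and treatment. Mx1 lies between 6.12 and 6.43 in the KO and vehicle macrophage arrays and between 10.47 and 11.87 in the 4 B10.Q macrophage arrays with IFNα.

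At 5 h, 88 genes rose and 0 fell in B10.Q macrophages against vehicle, with 414 at an unadjusted p under 0.05. Large rises were those of Rtp4 (30.6-fold, 4.93 ± 0.25, n = 2, limma adjusted p = 1.50e-05), Mx1 (at least 22.6-fold, 4.50 ± 0.26), Usp18 (20.9-fold, 4.38 ± 0.42), Ifit1 (at least 20.2-fold, 4.34 ± 0.42) and Oasl2 (15.7-fold, 3.98 ± 0.34). Of the 88, 71 were also among the 84 genes of 2 h, where 0.702 would be shared by chance with independent draws. The shared vehicle arrays link both times. Simulations without any effect gave a mean of 0.02 shared genes over 50 draws. Few genes can pass the adjusted threshold in such draws, so they cannot show how far the shared vehicle arrays raise the overlap. The 17 others included Zbp1, a sensor that starts necroptosis (2.15 ± 0.34), Mlkl, the protein that breaks the membrane in that form of death (0.95 ± 0.16), Fcgr1, a receptor for IgG (1.40 ± 0.27), and Pde7b. At 2 h Zbp1 was at 1.74 ± 0.34 with an adjusted p of 0.0509 and Mlkl at 0.78 ± 0.16 with 0.0695.

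Antiviral effectors again had 21 of 34 genes up and 27 adjusted over the list alone (median 1.54, adjusted p = 0.0807 with an estimated correlation). Oas2 was up by 3.55 ± 0.28, Cmpk2 by 2.65 ± 0.40, Xaf1 by 2.60 ± 0.22, and, from the same low vehicle values as at 2 h, Ifit3 by at least 3.85 ± 0.58, Rsad2 by at least 3.73 ± 0.45 and Mx2 by at least 3.56 ± 0.24. Nucleic acid sensing had 13 of 23 genes up and 15 adjusted over the list alone (median 0.94, adjusted p = 0.0807 with an estimated correlation). Ifi205 rose by at least 3.49 ± 0.51, Ifi209 by 2.27 ± 0.30 and Dhx58, a regulator of RIG-I, by 2.00 ± 0.26. In the PARP, TRIM and Schlafen families 15 of 24 rose and 20 adjusted over the list alone (median 1.20, adjusted p = 0.0807 with an estimated correlation). Slfn5 was up by 3.58 ± 0.28, Slfn1 by 2.41 ± 0.25, Slfn8 by 1.96 ± 0.16 and Parp14 by 1.78 ± 0.22. Irf7 (2.83 ± 0.28), Stat2 (1.87 ± 0.26) and Irf9 (1.54 ± 0.20) were the 3 of 21 signalling genes that rose, with 4 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). Irgm1 (2.07 ± 0.38) and Mitd1 (0.98 ± 0.16), which is not a GTPase, were the 2 of 8 members of the GBP and IRG list that rose, with 6 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). Among chemokines 0 of 18 were called by limma and 4 adjusted over the list alone, with a median of 0.44 (adjusted p = 0.229 with an estimated correlation). Ccl2 was at 1.20 ± 0.42 and Il15 at 1.11 ± 0.24. H2-T24 rose by 2.26 ± 0.21 and Gm12250 by 2.98 ± 0.44. Leaving out any of the 4 arrays lowered the count: 33 without vehicle array 1, 34 without vehicle array 2, 38 without IFNα array 1 and 29 without IFNα array 2. The replicate block gave 81 genes, and a fit of only these groups gave 203.

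Between 2 h and 5 h, 1 gene changed in B10.Q macrophages with limma: Pde7b, a phosphodiesterase that breaks down cyclic AMP, rose 4.42-fold (2.14 ± 0.12, n = 2, adjusted p = 6.40e-05). Of the 84 genes of 2 h, which the same 2 h arrays had selected, 0 were called between the times, with 6 higher and 7 lower at an unadjusted p under 0.05. Over all genes 529 had an unadjusted p under 0.05, where 527 would by chance. Clock genes had a list median of 0.55, with 0 of 13 called over all genes and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.254 with an estimated correlation). Nr1d1 was at 1.69 ± 0.41, Nr1d2 at 1.23 ± 0.25, Dbp at 1.13 ± 0.32 and Arntl at -0.69 ± 0.22. Against vehicle, whose pair joins an array of 2 h and an array of 5 h, Nr1d1 was at -0.98 ± 0.41 at 2 h and at 0.71 ± 0.41 at 5 h. Nr1d1 read 9.64 in the vehicle array of 2 h and 11.07 in that of 5 h, against 9.10 and 9.66 with IFNα at 2 h and 11.16 and 10.98 at 5 h, so its difference between the times was present without IFNα. The count was 2 without IFNα 2 h array 1, 5 without IFNα 2 h array 2, 40 in a fit of only these groups and 3 in a fit of all 16 arrays. The replicate block gave 1.

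The difference of responses asks whether the 2 h change in B10.Q macrophages exceeded that in KO macrophages. It was higher for 43 genes and lower for 0 of 10531, with 646 at an unadjusted p under 0.05. Rtp4 responded 35.4-fold more in B10.Q (5.14 ± 0.36, n = 2 per group) and Usp18 22.7-fold (4.50 ± 0.59). The difference was 5.42 ± 0.37 for Mx1 (limma adjusted p = 2.70e-04), 5.14 ± 0.59 for Ifit1, 4.63 ± 0.33 for Mx2 and 4.48 ± 0.64 for Rsad2, sizes that are uncertain because B10.Q vehicle values of these 4 lay below the lower quartile. Of the 43 genes, 41 had risen in B10.Q at 2 h, a share that the B10.Q arrays common to both contrasts favour. In the KO arrays the 84 genes that rose in B10.Q at 2 h had a median of -0.20, with 19 above and 65 below 0, 0 called by limma, and 1 higher and 10 lower at an unadjusted p under 0.05. The highest of them was at 0.60 and the lowest at -0.98. Untreated levels of the 84, B10.Q against KO, had a median of -0.09, with 57 below and 27 above 0, 8 lower and 2 higher at an unadjusted p under 0.05, and 1 call, Ms4a6c at -1.75 ± 0.23. The same B10.Q vehicle arrays had helped to select the 84 genes, which favours values below 0.

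By group, 12 of 34 antiviral effectors passed, and 25 did adjusted over the list alone (median 1.74, adjusted p = 0.132 with an estimated correlation). Oasl2 differed by 3.62 ± 0.47, Cmpk2 by 3.59 ± 0.56, Oas2 by 2.96 ± 0.40 and Xaf1 by 2.80 ± 0.30. The PARP, TRIM and Schlafen families had 9 of 24 members past the test and 19 adjusted over the list alone (median 1.24, adjusted p = 0.119 with an estimated correlation). Slfn5 differed by 3.23 ± 0.40, Slfn1 by 3.10 ± 0.35, Slfn9 by 3.01 ± 0.46 and Slfn3 by 2.58 ± 0.33. Nucleic acid sensing had 4 of 23 past the test and 14 adjusted over the list alone (median 1.33, adjusted p = 0.119 with an estimated correlation), among them Ifi209 (2.55 ± 0.43) and Dtx3l (1.98 ± 0.27). Irf7 (3.23 ± 0.40), Stat2 (2.29 ± 0.37) and Irf9 (2.29 ± 0.28) were the 3 of 21 signalling genes that passed, with 5 adjusted over the list alone (median 0.00, mean 0.52, adjusted p = 0.267 with an estimated correlation). Gm12250 differed by 4.08 ± 0.62, H2-T24 by 2.18 ± 0.29 and Axl by 1.51 ± 0.24. Axl itself changed by 0.40 ± 0.17 within B10.Q and by -1.11 ± 0.17 in KO, neither called. Of 8 members of the GBP and IRG list 0 passed with limma and 7 did adjusted over the list alone (median 2.19, adjusted p = 0.212 with an estimated correlation). In KO array 2 without IFNα their median lay 0.94 above that of array 1. Cell cycle genes had 0 of 25 past the test and 13 higher adjusted over the list alone (median 0.71, adjusted p = 0.178 with an estimated correlation). Their median change was 0.10 within B10.Q and -0.65 in KO. The count was 94 without KO IFNα array 1, 491 without KO IFNα array 2, 8 without KO array 2 titled without IFNα, 90 without B10.Q IFNα array 2, and 9 and 11 without the vehicle arrays 1 and 2. The replicate block gave 41. Strain, age and receptor differ together between these mice, and 1 of the 2 B10.Q vehicle arrays was taken at 5 h. The titles of the KO controls name no vehicle.

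**Figure D2:**
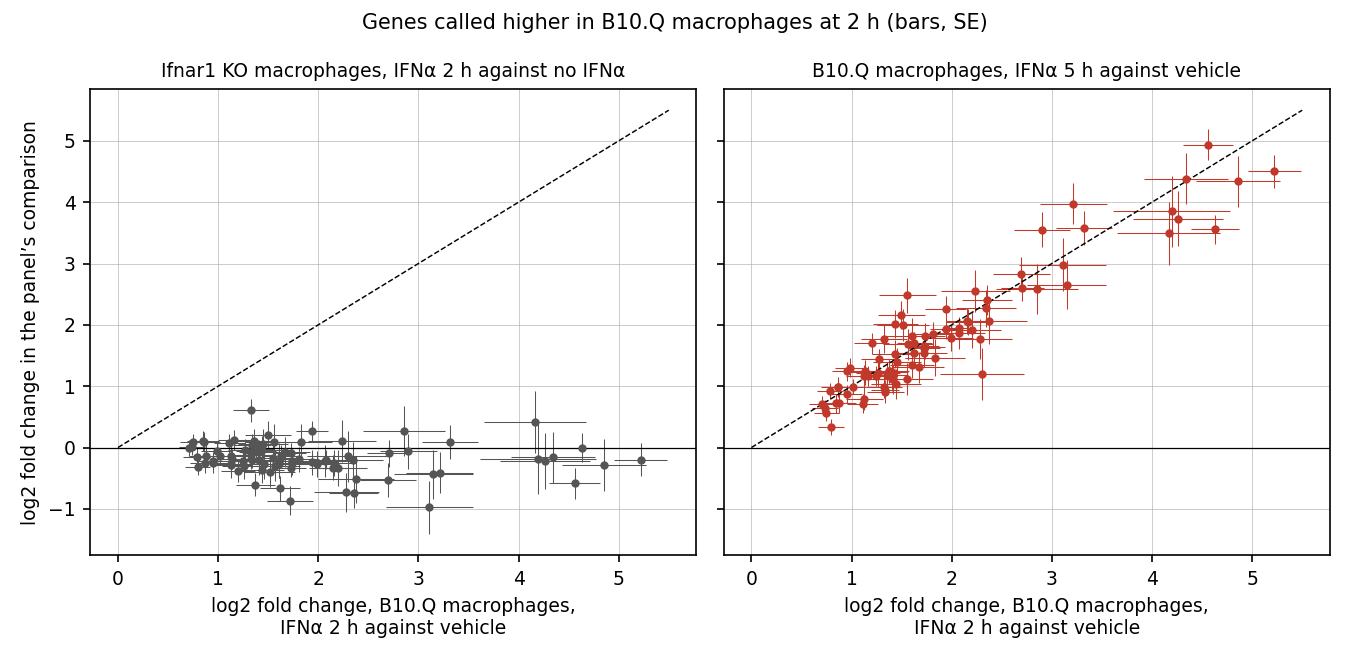
Log2 change of the 84 genes that rose in B10.Q macrophages at 2 h (horizontal) against their change in KO macrophages and in B10.Q macrophages at 5 h (vertical), 1 point per gene. The median is -0.20 in KO and 1.63 in B10.Q at 5 h.

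**Figure D3:**
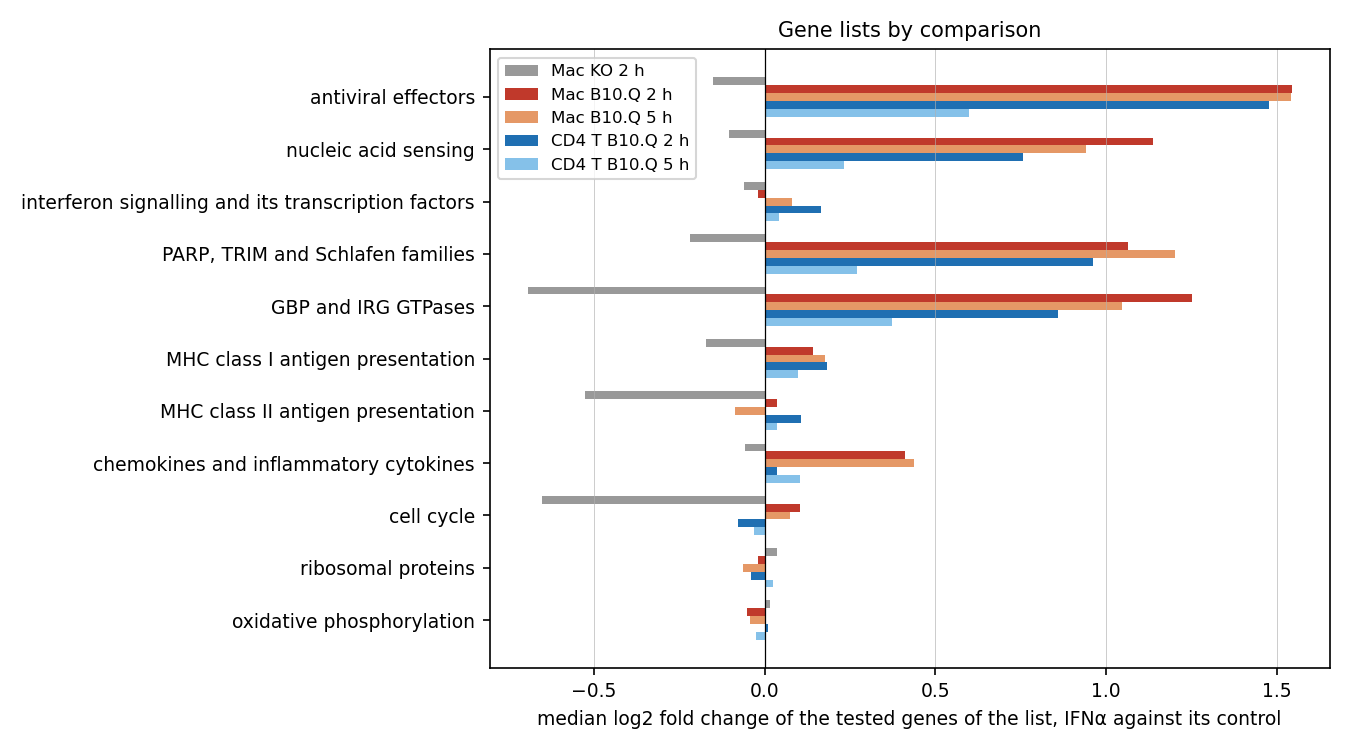
Median log2 change of gene lists in each comparison with vehicle or its KO counterpart. Antiviral effectors had medians of 1.54 at both times in B10.Q macrophages, 1.48 and 0.60 in T cells at 2 h and 5 h, and -0.15 in KO macrophages.

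Macrophages of B10.Q mice with vehicle and of KO mice titled without IFNα, called untreated here, were compared. The KO titles name no vehicle, so a vehicle injection in B10.Q alone is confounded with the other differences. With limma 29 genes were higher and 28 lower in B10.Q, with 1215 at an unadjusted p under 0.05 where 527 would by chance. The largest difference was in MHC class II presentation, the display of peptides to CD4+ T cells. H2-Ab1 was 10.6-fold lower in B10.Q (-3.41 ± 0.23 log2, n = 2, adjusted p = 9.02e-05), Cd74, the invariant chain, 4.75-fold lower (-2.25 ± 0.20, adjusted p = 5.92e-04), H2-Eb1 4.75-fold lower (-2.25 ± 0.17) and H2-Aa 3.42-fold lower (-1.78 ± 0.24). H2-Ob was at -1.37 ± 0.11. H2-Ab1 lay between 7.53 and 8.48 in the 6 B10.Q macrophage arrays and between 10.86 and 11.77 in the 4 KO arrays. Of 8 class II genes 5 were lower, and 7 were lower adjusted over the list alone (median -1.57, adjusted p = 0.0807 with an estimated correlation). H2-DMa was at -1.03 ± 0.19 and Ciita at -1.01 ± 0.26, with adjusted p of 0.0566 and 0.159.

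**Figure D4:**
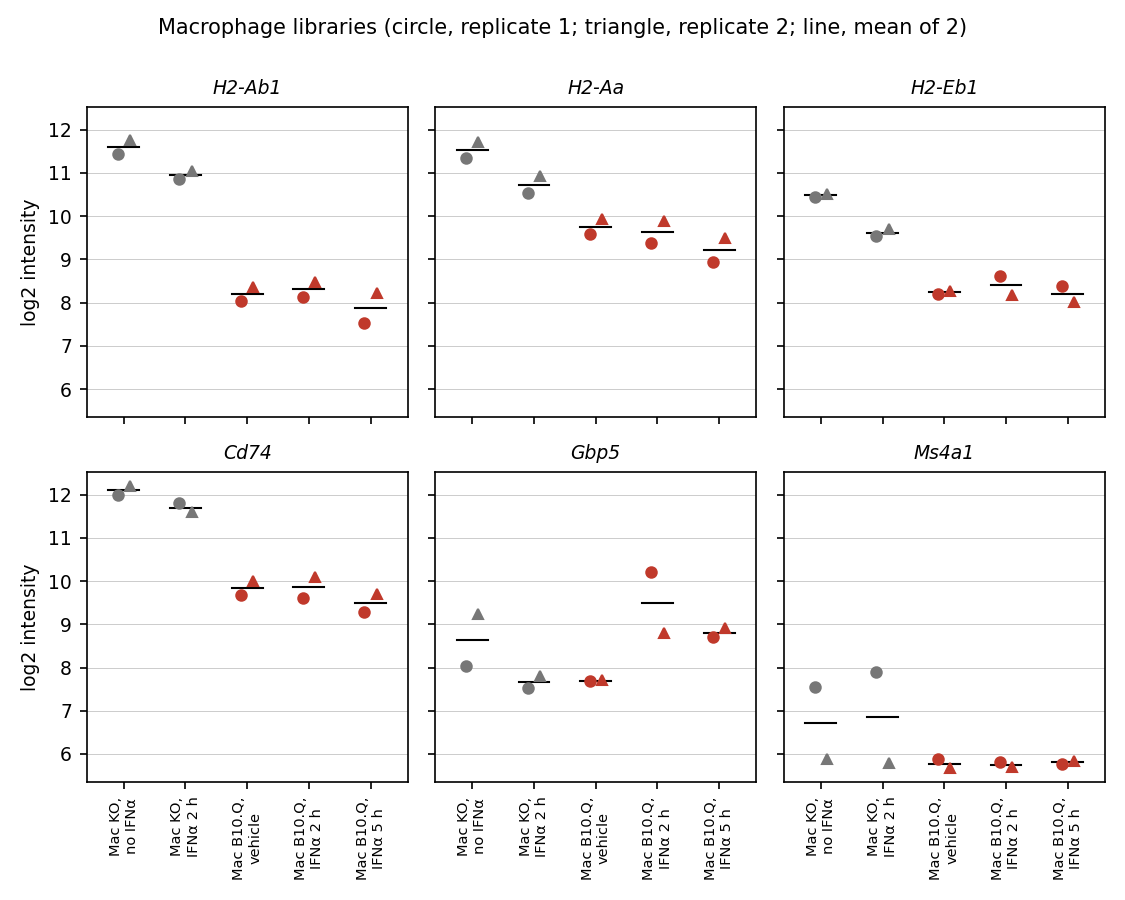
Log2 intensity of MHC class II genes in each of the 10 macrophage arrays, 1 point per array. H2-Ab1 is at 10.86 to 11.77 in the KO arrays and at 7.53 to 8.48 in the B10.Q arrays, with and without IFNα.

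Outside class II, Coro2b, which binds actin, was 8.16-fold higher in B10.Q (3.03 ± 0.14), Hpgd, which inactivates prostaglandins, 6.22-fold (2.64 ± 0.17), and Tdo2, which degrades tryptophan, 5.57-fold (2.48 ± 0.17). Car12, a carbonic anhydrase, was higher by 1.97 ± 0.27, P2rx1, an ATP-gated channel, by 1.69 ± 0.17, Olr1, a receptor for oxidised lipoprotein, by 1.64 ± 0.29, Vcan, a matrix proteoglycan, by 1.43 ± 0.21, Cnr2, a cannabinoid receptor, by 1.26 ± 0.11, and Trem2, a lipid receptor, by 1.22 ± 0.14. Fuca1 (1.29 ± 0.14), Ada (1.22 ± 0.15), Pigp (1.21 ± 0.14) and Pi16 (1.18 ± 0.19) were higher too. Lower in B10.Q were Aoah, which deacylates endotoxin (-2.22 ± 0.12, 4.67-fold), Cd209f (-2.03 ± 0.32), Ms4a6c (-1.75 ± 0.23), Fblim1 (-1.65 ± 0.17), Folr2, a folate receptor (-1.44 ± 0.15), Wee1, an inhibitor of mitosis (-1.05 ± 0.19), and Jun (-0.92 ± 0.14). Cell cycle genes had 1 of 25 lower, Mcm5 at -0.71 ± 0.12, and 19 lower adjusted over the list alone (median -0.55, adjusted p = 0.210 with an estimated correlation). The same KO arrays titled without IFNα enter the list's KO change (median -0.65) and its difference of responses (median 0.71). These shifts are therefore not independent results. Of 5 monocyte markers Fcrls was lower (-0.82 ± 0.13) with a median of -0.15 (adjusted p = 0.468 with an estimated correlation). B cell markers, high in KO array 1, had a median of -0.29 with 0 of 5 called (adjusted p = 0.455 with an estimated correlation). Antiviral effectors had a median of -0.06 with 0 of 34 called (adjusted p = 0.897 with an estimated correlation). Strain, age, receptor, collection time, vehicle injection and the KO label conflict are confounded here. Whether the KO and B10.Q arrays were normalised together is not stated, so differences in array processing also stay open. The B10.Q vehicle pair joins an array of 2 h and an array of 5 h, while the preparation text of both KO arrays states 2 h. Clock genes had 0 of 13 called, with 2 higher and 2 lower adjusted over the list alone (median 0.21, adjusted p = 0.808 with an estimated correlation). Nr1d1 was at 1.68 ± 0.41 and Per2 at -0.69 ± 0.16, neither called. The count was 33 and 23 without KO array 1 or 2, 27 and 21 without vehicle array 1 or 2, 30 with a filter at the 70th percentile, 198 in a fit of only these groups, 150 in a fit of all 16 arrays, and 59 with the replicate block.

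CD4+ T cells were taken from the spleens of B10.Q mice under the same injections. At 2 h, 28 genes rose and 1 fell of 10112 tested, with 614 at an unadjusted p under 0.05 where 506 would by chance. Ifit1 rose 37.9-fold (5.24 ± 0.28, n = 2, limma adjusted p = 7.71e-04), Usp18 10.8-fold (3.43 ± 0.27), Rtp4 10.2-fold (3.34 ± 0.15, adjusted p = 5.87e-04), Mx2 at least 6.28-fold (2.65 ± 0.31) and Rsad2 by at least 2.61 ± 0.21, the last 2 from vehicle values below the lower quartile. The 1 gene that fell was Hs3st3b1, a heparan sulfate sulfotransferase, at -0.63 ± 0.09 (adjusted p = 0.0449). Apart from leaving out arrays, 4 of 10 alternatives called Hs3st3b1. In all 29 both IFNα arrays lay beyond both vehicle arrays, as they did for 1465 of all genes upward and 1964 downward, where chance gives 16.7% each way. Of the 27 T-cell rises that were also tested in macrophages, 23 had risen there at 2 h, where 0.21 would be shared by chance over 9368 genes.

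Macrophage genes were present in the T-cell arrays of 2 h. Lyz2, the lysozyme of myeloid cells, read 12.20 and 10.02 there against 7.34 to 7.67 in the 4 other T-cell arrays. Prg4 read 10.99 and 8.74, Alox15 10.69 and 8.32, and Adgre1 (F4/80) 8.63 and 6.82. The mean of 13 peritoneal macrophage markers was 8.59 and 7.54 against 7.05 to 7.08. Lyz2 was at 3.61 ± 0.58 with an adjusted p of 0.0709, Alox15 at 2.41 ± 0.65 and Prg4 at 2.11 ± 0.59. These arrays were the same in which the antiviral genes were high.

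**Figure D5:**
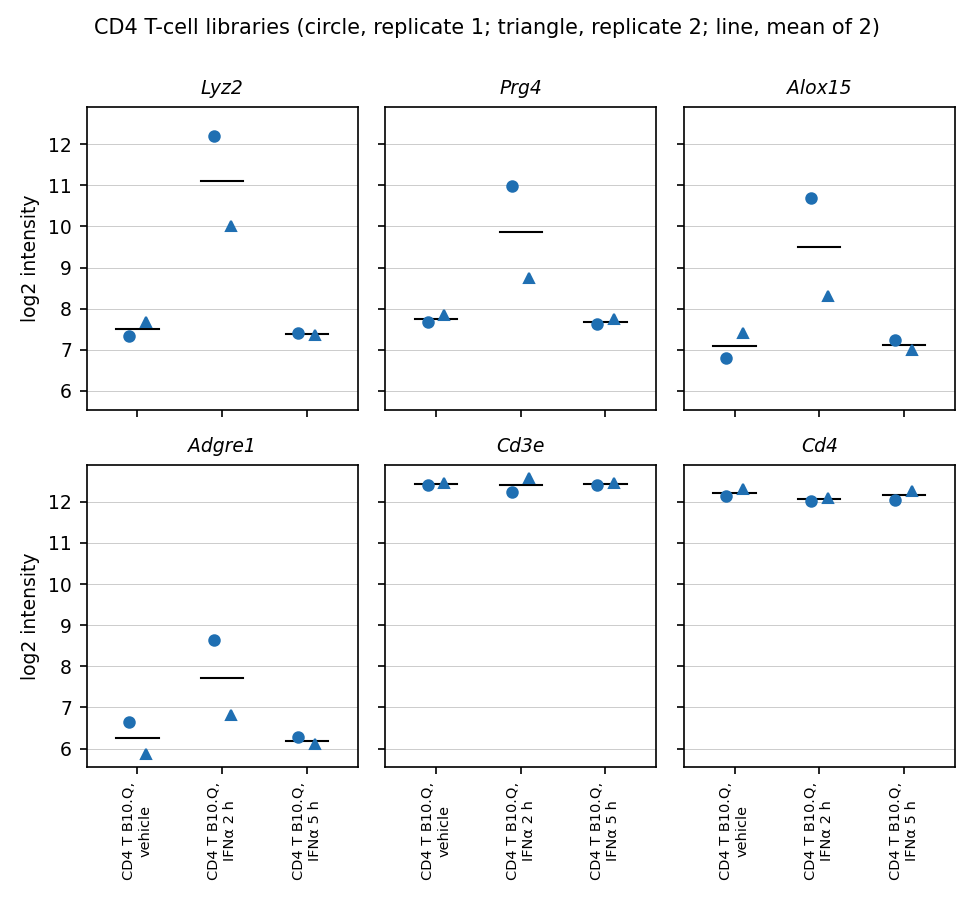
Log2 intensity of peritoneal macrophage markers in the 6 T-cell arrays, 1 point per array. Lyz2 is at 12.20 and 10.02 in the arrays of 2 h and at 7.34 to 7.67 in the others.

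Antiviral effectors had 9 of 32 genes up over all genes and 29 adjusted over the list alone (median 1.48, adjusted p = 0.229 with an estimated correlation). Cmpk2 rose by 2.40 ± 0.21, Xaf1 by 2.05 ± 0.17 and Oas1b by 1.68 ± 0.15. Ifit3 was at 3.44 ± 0.50 with an adjusted p of 0.0543. In the same arrays the mean of the macrophage markers was 8.59 and 7.54. Nucleic acid sensing had 4 of 19 up and 15 adjusted over the list alone (median 0.76, adjusted p = 0.212 with an estimated correlation), with Dhx58 at 1.74 ± 0.18 and Trim25 at 1.44 ± 0.14. The PARP, TRIM and Schlafen families had 4 of 23 up and 18 adjusted over the list alone (median 0.96, adjusted p = 0.236 with an estimated correlation), Slfn8 among them (1.44 ± 0.16). Irf7 (1.87 ± 0.16) and Irf9 (1.20 ± 0.09) were the 2 of 19 signalling genes that rose, with 3 adjusted over the list alone (median 0.17, adjusted p = 0.166 with an estimated correlation). Of 10 members of the GBP and IRG list only Mitd1, which is not a GTPase, rose (0.89 ± 0.12), Irgm1 was at 1.80 ± 0.26 with an adjusted p of 0.054, and 9 were higher adjusted over the list alone (median 0.86, adjusted p = 0.297 with an estimated correlation). Cxcl10, which attracts activated T cells, rose by 0.86 ± 0.12, the 1 of 7 chemokines and cytokines called. Apart from leaving out arrays, 5 of 9 alternatives called Cxcl10. Adjusted over the list alone, 2 chemokines and cytokines were higher and 1 lower (median 0.04, adjusted p = 0.543 with an estimated correlation). H2-T24 rose by 1.68 ± 0.20, Ifi213 by 1.79 ± 0.15, Ifi214 by 1.60 ± 0.22, Phf11c by 1.59 ± 0.18 and Gm12250 by 1.67 ± 0.23. With the estimated macrophage RNA subtracted, an alternative chosen after seeing the data, 24 of the 28 rises were called, and the adjusted p of Gm12250, Dtx3l, Mitd1 and Ifi214 rose to between 0.0528 and 0.0554. The count was 71 without IFNα array 1, 1817 without IFNα array 2 (599 higher, 1218 lower), 0 without vehicle array 1, 2 without vehicle array 2, 2 in a fit of only these groups and 50 in a fit of all 16 arrays, and 36 with the replicate block.

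At 5 h, 2 genes rose in T cells and 0 fell with limma, with 387 at an unadjusted p under 0.05 where 506 would by chance. Rtp4 was 4.42-fold higher (2.14 ± 0.15, n = 2, adjusted p = 0.0073), and Neb, which encodes the muscle protein nebulin, was 2.87-fold higher (1.52 ± 0.11, adjusted p = 0.0073). Neb read 8.93 and 8.77 at 5 h against 7.34 and 7.32 with vehicle. Ifit1 was at 2.61 ± 0.28, Bcl3, a nuclear partner of NF-kappaB, at 1.25 ± 0.14 and Irf9 at 0.82 ± 0.09, each with an adjusted p of 0.0579. Of the 28 genes that rose at 2 h against the same vehicle arrays, 1 was called at 5 h. All 28 lay above 0 at 5 h, with a median of 0.655, and 24 were higher at an unadjusted p under 0.05. Antiviral effectors had 1 of 32 called and 13 adjusted over the list alone (median 0.60, adjusted p = 0.301 with an estimated correlation). Nucleic acid sensing had 0 of 19 and 4 adjusted over the list alone (median 0.23, adjusted p = 0.410 with an estimated correlation), and the PARP, TRIM and Schlafen families 0 of 23 and 6 adjusted over the list alone (median 0.27, adjusted p = 0.453 with an estimated correlation). GBP and IRG GTPases had 0 of 10 called and 0 adjusted over the list alone (median 0.37, adjusted p = 0.458 with an estimated correlation). Without any 1 of the 4 arrays the count was 0. It was 1 with a filter at the 70th percentile, 4 after subtraction of array medians, 63 in a fit of only these groups, 6 in a fit of all 16 arrays and 3 with the replicate block.

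Between 2 h and 5 h in T cells, 1 gene changed with limma, Neb, which rose 2.70-fold (1.43 ± 0.11, n = 2, adjusted p = 0.022), and 996 genes had an unadjusted p under 0.05 where 506 would by chance. Ifit1 was at -2.63 ± 0.28 and Rsad2 at -2.11 ± 0.21, each with an adjusted p of 0.0695. Mx2 (-2.02 ± 0.31) and Lyz2 (-3.73 ± 0.58) had an adjusted p of 0.201, and Usp18 (-1.95 ± 0.27) one of 0.169. Of the 28 genes that rose at 2 h, which the same 2 h arrays had selected, 0 were called between the times, with 27 lower at an unadjusted p under 0.05. Antiviral effectors had 0 of 32 called and 19 lower and 1 higher adjusted over the list alone (median -0.68, adjusted p = 0.368 with an estimated correlation). Nucleic acid sensing had 0 of 19 called and 13 lower adjusted over the list alone (median -0.58, adjusted p = 0.262 with an estimated correlation), and the PARP, TRIM and Schlafen families 0 of 23 and 9 lower adjusted over the list alone (median -0.57, adjusted p = 0.318 with an estimated correlation). The mean of the macrophage markers, 8.59 and 7.54 at 2 h, was 7.08 and 7.05 at 5 h. The count was 27 without IFNα 2 h array 1, 1641 without IFNα 2 h array 2 and 0 without either array of 5 h. No filter or subtraction of array medians gave 3, a filter at the 70th percentile or a fit of only these groups 0, all 16 arrays 7, and the replicate block 1.

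The responses of both B10.Q cell types were then set against each other. At 2 h the macrophage response exceeded that of T cells for 3 of 11161 genes, and 0 were lower, with 815 at an unadjusted p under 0.05 where 558 would by chance. Mx1 differed by 4.30 ± 0.42 (n = 2 per group, limma adjusted p = 0.003), Dck, a kinase that salvages deoxynucleosides, by 1.88 ± 0.24 (adjusted p = 0.0223), and Trex1, a nuclease that removes cytosolic DNA, by 1.34 ± 0.17 (adjusted p = 0.022). Mx1 read 7.23 and 6.41 in T cells at 2 h against 5.96 and 5.84 with vehicle. Vehicle values of Mx1 lay below the lower quartile in both cell types, so the size of its difference is uncertain. Antiviral effectors had 1 of 35 past the test, with 7 higher and 2 lower adjusted over the list alone (median 0.21, adjusted p = 0.656 with an estimated correlation). Peritoneal macrophage markers had a median of -0.45 with 0 of 13 called (adjusted p = 0.509 with an estimated correlation), and their mean was 8.59 and 7.54 in the T-cell arrays of 2 h. The count was 90 without macrophage IFNα array 2, 7 without macrophage IFNα array 1, 18 and 511 without T-cell IFNα array 1 or 2, and 1 without any 1 of the 4 vehicle arrays. It was 8 with macrophage RNA subtracted (chosen after seeing the data), 7 with no filter or every probe set, 6 with the trend model, 5 after subtraction of array medians, 1 in a fit of only these groups and 3 with the replicate block.

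At 5 h the macrophage response exceeded that of T cells for 27 genes and fell short for 1, with 556 at an unadjusted p under 0.05 where 558 would by chance. Oasl2 differed 9.05-fold (3.18 ± 0.47, n = 2 per group), Rtp4 6.92-fold (2.79 ± 0.27) and Pde7b 5.51-fold (2.46 ± 0.24). Mx1 differed by 4.31 ± 0.42 (limma adjusted p = 7.16e-04), Ifi205 by 3.47 ± 0.60 and Mx2 by 2.92 ± 0.45, sizes that are uncertain because vehicle values lay below the lower quartile in both cell types. Siglec1, a sialic acid receptor of macrophages, differed by 1.79 ± 0.18, Sp100 by 1.65 ± 0.20, Slfn1 by 2.27 ± 0.35, Ifi209 by 2.35 ± 0.38, Phf11d by 2.24 ± 0.34, Gm12250 by 2.39 ± 0.42, Ms4a6c by 2.36 ± 0.34 and Dck by 1.82 ± 0.24. Neb was the 1 gene with the smaller response in macrophages (-1.60 ± 0.14, adjusted p = 7.16e-04). Antiviral effectors had 8 of 35 past the test, with 21 higher and 1 lower adjusted over the list alone (median 1.12, adjusted p = 0.241 with an estimated correlation). Nucleic acid sensing had 3 of 23 and 12 adjusted over the list alone (median 0.65, adjusted p = 0.183 with an estimated correlation), and the PARP, TRIM and Schlafen families 3 of 24 and 12 adjusted over the list alone (median 0.64, adjusted p = 0.200 with an estimated correlation). GBP and IRG GTPases had 0 of 12 called and 1 adjusted over the list alone (median 0.49, adjusted p = 0.616 with an estimated correlation). The count was 6 without any 1 of vehicle array 1 of either cell type or the 4 arrays of 5 h, 7 without macrophage vehicle array 2 and 11 without T-cell vehicle array 2. It was 8 after quantile normalization, 17 with the trend model, 140 in a fit of only these groups, 14 in a fit of all 16 arrays and 31 with the replicate block.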

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

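Of the tests below, those of mixed macrophage RNA and of a response to IFNα in 1 KO array were written before their results were seen, and those of red pulp macrophages, the source of the called rises, probe mismatch, B cells, monocytes, other cell types and interferon gamma were chosen after.

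The difference between the 2 h responses of B10.Q and KO macrophages passed the test for 43 genes. It was 5.14 log2 for Rtp4, 4.50 for Usp18, 4.08 for Gm12250, 3.62 for Oasl2, 3.59 for Cmpk2, 3.23 for Slfn5, 3.23 for Irf7, 3.10 for Slfn1, 3.01 for Slfn9, 2.96 for Oas2 and 2.80 for Xaf1. For genes with B10.Q vehicle values below the lower quartile of their arrays, whose sizes are uncertain and not ranked, it was 5.42 for Mx1, 5.14 for Ifit1, 4.63 for Mx2 and 4.48 for Rsad2. Between 5 h and 2 h the test passed for 1 gene in macrophages, Pde7b at 2.14, and for 1 gene in T cells, Neb at 1.43. Macrophage and T-cell responses differed at 2 h for 3 genes, Dck at 1.88, Trex1 at 1.34 and, with low vehicle values in both cell types, Mx1 at 4.30. They differed at 5 h for 28 genes, among them Oasl2 at 3.18, Rtp4 at 2.79, Pde7b at 2.46, Gm12250 at 2.39, Ms4a6c at 2.36, Ifi209 at 2.35, Slfn1 at 2.27, Phf11d at 2.24, Dck at 1.82, Siglec1 at 1.79, Sp100 at 1.65, Neb at -1.60 and, with vehicle values below the lower quartile in both cell types or, for Ms4a6b, in macrophages, Mx1 at 4.31, Ifi205 at 3.47, Mx2 at 2.92 and Ms4a6b at 1.65. Of 1687 probe sets without exactly 1 symbol, which the comparisons left out, 18 were called higher by limma in B10.Q macrophages at 2 h, while 0 were in KO macrophages (37 higher and 38 lower at an unadjusted p under 0.05) and 2 of 1722 were in T cells at 2 h.

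Peritoneal macrophage markers were high in the T-cell arrays of 2 h, with Lyz2 at 12.20 and 10.02 against 7.34 to 7.67 in the other T-cell arrays. RNA of peritoneal macrophages mixed into these arrays is a candidate explanation: with a share of 2.25% estimated from 12 markers in array 1, the rise of 203 other macrophage genes differed from that of the mixture by a median of -0.09 log2, and 192 of them lay above the 4 other T-cell arrays. In array 2 the share was 0.392%, and 102 of the 203 did. As a ratio of log2 rises, the mixture gives a median of 2.26% of the observed rise of the 28 called genes and at most 15.8% for any of them. This argues against the mixture as the source of these rises. Red pulp macrophages of the spleen as the source of the peritoneal markers are argued against in array 1. There the highest rise of their 7 markers over the 4 other T-cell arrays was 0.16, against a median rise of 0.79 for the peritoneal list. In array 2 it was 0.14 against 0.17, too close to tell, and over both arrays 0.15 against 0.50, a gap of -0.35. This rule followed an earlier one, of which the red pulp median of 0.12 against vehicle (range -0.20 to 0.24) met neither side. Some of these cells passing the sort beside that RNA therefore stays open.

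MHC class II genes were lower in untreated B10.Q than KO macrophages, by a median of -2.01 over the 4 H2-encoded genes called. Probes that match the H2 alleles of B10.Q poorly cannot be the whole source, since Cd74, encoded outside H2, was at -2.25 ± 0.20. B cells in the KO arrays are argued against by the arrays numbered 2, where 13 B cell markers lay a median of 0.13 above the B10.Q arrays (range -0.14 to 0.35) while H2-Ab1 lay at least 2.56 above them, but a first rule had left this open, with 3 markers at or below and 6 above the highest B10.Q array in both KO arrays, and the median replaced it after that result was seen. A larger share of monocytes or small peritoneal macrophages in the KO arrays, cells that the ICAM2+ F4/80+ gate is meant to leave out, cannot be told apart, since 5 of their markers had a median of -0.15 (range -0.82 to 0.11) with 1 called lower. Strain, age, collection time, the missing receptor, the vehicle injection, array processing and a partial probe mismatch also stay open, untested.

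In KO array 2 titled without IFNα, the GBP and IRG list lay above KO array 1, by a median of 0.94 over 8 members, all 8 higher, with Iigp1 at 1.63 and Irgm1 at 1.52. A response to IFNα in that array is argued against by a median gap of 0.18 over the 84 genes that rose in B10.Q at 2 h, with Mx1 at 0.07 and Ifit1 at 0.05, although 68 of the 84 were higher in array 2. A larger share of another cell type is argued against by the highest median gap of any of 11 marker lists, 0.31 for platelets. Exposure of that animal to interferon gamma may be the cause, a hypothesis found and tested on these arrays: Ciita was 1.01 higher, class II genes a median of 0.27 higher, and Mx1, Mx2, Ifit1 and Rsad2 a median of 0.05. The design has no group with interferon gamma, and a wrong label of this array was not tested.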

How the results depend on the processing

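The subtraction of macrophage RNA and the crossed KO numbers were chosen after seeing the data, and every other alternative here was planned. Of 17693 values of named genes over the alternatives, 16420 kept their direction and their side of the threshold, 431 lost a call, 451 gained one, 0 called values turned over and 391 uncalled values changed sign. Only 2175 of the 17693 values belonged to genes called in the main fits, and the 431 lost calls are among these 2175. Counts that moved by over 1.5 times are given below, and the cause was not tested unless stated. No scaling moved the median of all genes by more than 0.1 log2.

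With the KO IFNα response at 0 genes, quantile normalization gave 1 and a fit of all 16 arrays 11. Other counts in the fit of all 16 arrays, which adds residual degrees of freedom, were 3 for macrophages at 5 h against 2 h, 72 for B10.Q against KO responses, 150 for untreated macrophages, 50, 6 and 7 for T cells at 2 h, 5 h and between them, and 14 for macrophage against T-cell responses at 5 h. In a fit of only the compared groups they were 203 for macrophages at 5 h, 40 between 5 h and 2 h, 198 for untreated macrophages, 2, 63 and 0 for T cells at 2 h, 5 h and between them, and 1 and 140 for macrophage against T-cell responses at 2 h and 5 h. A filter at the 70th percentile gave 30 for untreated macrophages, 1 for T cells at 5 h and 0 for T cells between the times. No filter gave 3 for T cells between the times and 7 for responses at 2 h. Subtraction of array medians gave 4 for T cells at 5 h, 3 between the times and 5 for responses at 2 h. The trend model gave 6 and 17 for responses at 2 h and 5 h, every probe set 7 at 2 h, and quantile normalization 8 at 5 h. Macrophage RNA subtracted gave 8 for responses at 2 h, with all 3 genes kept, 24 for T cells at 2 h and 1 between the times.

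Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 0 to 1191 genes for KO macrophages, 36 to 123 for B10.Q macrophages at 2 h, 29 to 38 at 5 h, 1 to 5 between the times, 8 to 491 for B10.Q against KO responses, 21 to 33 for untreated macrophages, 0 to 1817 for T cells at 2 h, 0 to 0 at 5 h, 0 to 1641 between the times, and 1 to 511 and 6 to 11 for macrophage against T-cell responses at 2 h and 5 h. For gene lists it gave 93 to 110 tests past the threshold. With the number in the titles as a replicate block, counts were 0, 75, 81, 1, 41, 59, 36, 3, 1, 3 and 31 in the order of the comparisons, and 102 for lists. Replicate differences of the groups correlated between -0.29 and 0.18 over genes, and the KO pair at -0.29, where crossing the numbers in the replicate block gave 0 genes. Of the 236 list tests, 101 passed at the preset correlation, 0 with an estimated correlation and 13 with fry. In simulations of 2 arrays per group, 10% to 86.4% of 1.5-fold changes were recovered over the contrasts.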

Other observations

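The test of neighbouring genes here was chosen after the untreated difference between the mice was seen.

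Gene groups outside interferon biology showed few calls. Clock genes in T cells had a median of -0.06 at 2 h and 0.04 at 5 h, with 0 of 10 called by limma and 0 adjusted over the list alone, while in macrophages between the times Nr1d1 was at 1.69 ± 0.41 with an adjusted p of 0.731, and the vehicle arrays of 2 h and 5 h read 9.64 and 11.07. Monocyte markers in B10.Q macrophages at 5 h had a median of -0.42 with 0 of 5 called (adjusted p = 0.177 with an estimated correlation). Retnla, an alternative activation marker, was at -0.42 ± 0.15 and Ccr2, the receptor of Ccl2, at -0.70 ± 0.36. Lymphocyte activation genes in T cells at 5 h had a median of 0.05, with 0 of 22 called and 1 adjusted over the list alone, Bcl3 at 1.25 ± 0.14 (adjusted p = 0.274 with an estimated correlation). Glucocorticoid response genes, a sign of stress or handling, had medians of 0.13 and 0.33 in B10.Q macrophages at 2 h and 5 h with 0 of 14 called at either time (adjusted p = 0.553 and 0.453 with an estimated correlation). Mt2, a metallothionein of that list, was at 1.38 ± 0.23 in KO macrophages with an adjusted p of 0.174. Immediate early genes had medians of -0.02 and -0.01 in B10.Q macrophages at 2 h and 5 h, heat shock genes -0.16 and -0.13, sterol synthesis -0.14 and 0.07, oxidative phosphorylation -0.05 and -0.04, and ribosomal proteins -0.02 and -0.06, with 0 members called in any of these.

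Markers of other cells were compared across the arrays. The mean of 11 CD4 T cell markers was 11.55 to 11.76 in T-cell arrays and 6.47 to 6.82 in macrophage arrays. In macrophage arrays the mean of 8 NK cell markers lay between 5.35 and 5.67, of 8 dendritic cell markers between 7.11 and 7.34, of 12 eosinophil and mast cell markers between 5.79 and 6.07, of 4 erythroid markers between 6.81 and 7.14, of 6 platelet markers between 7.85 and 8.15, and of 6 plasma cell markers between 7.40 and 7.60. In T-cell arrays these means lay between 6.24 and 6.66, 6.69 and 6.88, 5.88 and 5.93, 6.88 and 6.97, 6.71 and 7.25, and 7.31 and 7.48 in the same order. The mean of 9 neutrophil markers was 6.65 to 7.48 in macrophage arrays and 5.96 to 6.15 in T-cell arrays. The fixed list of type I and II interferon genes, too few of which were tested, also held Ifnl2, which encodes a type III interferon. In KO macrophages Ifna5 was at 0.04 ± 0.15 and Ifnl2 at 0.09 ± 0.13. The mean of 7 red pulp macrophage markers was 7.47 to 7.79 in macrophage arrays and 6.95 to 7.20 in T-cell arrays. The mean of 13 B cell markers was 7.72 and 7.49 in the KO arrays numbered 1 and 6.96 to 7.19 in the 8 other macrophage arrays.

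By its label the KO line carries an Ifnar1 targeted in cells of another strain, so genes flanking the targeted locus may keep that strain's form and differ from B10.Q for that reason. Among the 88 tested genes within 50 on either side of Ifnar1 in the order of GRCm38.p6, 3 differed between untreated B10.Q and KO macrophages, where 0.477 would by chance (one-sided Fisher exact p = 0.0119). They were Gbe1, Mirlet7c-1 and Pigp. Around H2-Ab1, without the class II genes themselves, 1 of 96 neighbours differed, D17H6S56E-5, where 0.475 would by chance (one-sided Fisher exact p = 0.38), and this cannot be told apart from chance because 1 gene is too few. Which form of these genes each mouse carries was not measured.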
